A study of Mus musculus with 6 samples.

How the data were processed

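RNA from 6 samples of cultured mouse embryonic NSP cells was measured on 1-colour Affymetrix arrays, 6 days after infection. In 3 samples the lentivirus carried a control shRNA and in 3 a REST shRNA. Per the labels' protocols, total RNA was extracted with Trizol and the amplified cDNA was fragmented and labelled with biotin using an Encore kit. The values are those of the deposited series table, in log2 units per probe set. The unit was read from the range of the values, 1.00 to 14.2, since the background correction, the summary of probes and the normalization between arrays are not given in the sources used here. The arrays' sorted values differed from their mean by 0.0224 on average and by 0.112 at most, so the arrays share nearly one distribution and were used without further scaling. A table forced to one distribution hides a change of total RNA per cell, and differences are relative to the other genes of the same array.

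Groups and replicate numbers were taken from the sample titles, and every column of the table matched 1 sample. No pair of arrays held the same values, with Pearson correlations between arrays from 0.955 to 0.993. The labels do not say whether the 3 samples of a group came from separate embryos or cultures, so p-values measure only the spread between these samples, which may be technical.

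Probe sets were named from the platform annotation of the array, with symbols brought up to date by gene number through a RefSeq table of assembly GRCm38.p6, used for names only. In this annotation 34958 probe sets had 1 gene, 932 had several and were left out, and 9211 were not listed and are unnamed here. Of the probe sets with 1 gene, 34754 found their gene number in the RefSeq table, and 0 symbols changed. For each of the 18194 genes the probe set with the highest mean over all 6 arrays was used, a choice made without regard to group. 9012 genes had more than 1 probe set, and the report says where another probe set of a named gene had the opposite sign. No filter on dim genes was applied. The highest value of 27 bacterial control probe sets, 3.24, served as a background reference, and 13832 genes had a mean above it. Signals near this reference understate differences.

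The fit was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values and the group as the sole term, 4 residual and 2.7 prior degrees of freedom, two-sided, and Benjamini-Hochberg adjustment over all genes. A call is an adjusted p under 0.05. The 22 gene lists were tested with camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, each adjusted over the 22 lists. Counts of members adjusted over the list alone used the same p-values. Of 590 list entries 550 were matched, 4 of them through an older symbol, and the other 40 were not analysed here. Btg2 and Sesn2 stand in 2 lists each. The probe sets of Rest were tested in a fit over all probe sets, and by an exact permutation test, which cannot go below 0.1 with 3 against 3 arrays.

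The genes named were set by a rule. Rest comes first. Then come up to 15 genes per direction past the threshold whose groups do not overlap, or, with none past it, the 5 genes per direction with the smallest unadjusted p, with predicted gene models passed over (1 was, among the lower genes). Then come the members of each list with the smallest p, 2 per list where none was called. Genes outside the rule are named where they make up a short count or contrast within a list, and were chosen after their values were seen. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

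Samples in different groups share replicate numbers. Deviations from the group means correlated at 0.108, 0.365 and 0.504 over genes for the pairs numbered 1, 2 and 3, all above 0.1, so the numbers were taken to pair the arrays. The pairing rests on the titles and on this correlation, with pair 1 barely past the limit. Control array 1 correlated more with REST shRNA array 2, at 0.268, than with its own number, so the pairing of that number is weakly borne out. The fit with the replicate number as a block was an alternative, and its values stand beside results whose call it changed.

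The alternatives were the replicate block, other scalings, filters on dim genes, variance models, array weights, other choices of probe set, an unequal-variance test per gene, leaving out probe sets that can match several transcripts, and leaving out each array. Leaving out both arrays of a number, and covariates for the cell cycle and for the Gapdh 3' minus 5' signal, were added after seeing the data.

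The steps were tested on simulated data, in 20 simulated tables of 18194 genes with the means and spreads of these arrays, independent noise and 200 changed genes. The test recovered 25.6% of the 100 genes changed 2-fold and 73.6% of the 100 genes changed 4-fold at the adjusted threshold, with 5.25 false calls per table on average. The 95% intervals covered the true value for 94.6% of genes. Real arrays share variation across genes, which the simulation leaves out. No genome was used, and no coordinates are given.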

Results

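Gene expression was measured on 6 Affymetrix mouse arrays hybridised with RNA from cultured NSP cells, an abbreviation that in this field commonly stands for neural stem and progenitor cells. The cells came from brains of mouse embryos, were grown on coated dishes until confluent, split, and infected overnight with a lentivirus that expressed a short hairpin RNA (shRNA). In 3 samples the hairpin was a control and in 3 it was directed against REST, and RNA was taken 6 days after infection. The labels do not say whether the samples of a group came from separate cultures. REST is a zinc finger repressor that binds a DNA element called RE1 near many neuronal genes and keeps them low in cells that are not neurons. The comparison asks which transcripts differ once REST is targeted. Values are log2 signals of probe sets, a probe set being the group of short probes that reads one transcript, and 18194 genes were tested. The 3 arrays per group limit the precision of every value below.

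The targeted transcript was lower in the REST shRNA arrays. All 4 probe sets of Rest lay lower in each of the 3 pairs of arrays with the same replicate number. The brightest one read 8.86 ± 0.09 (SD, n = 3) on the log2 scale in the control arrays and 8.18 ± 0.47 (SD, n = 3) in the REST shRNA arrays. Its level with REST shRNA was 62.5% of control, and the other probe sets read 57.3%, 66.8% and 71.5% of control. Adjusted over the 4 probe sets alone, the limma p was 0.00699 for the probe set at 57.3% and 0.0322 for each of the other 3. With the replicate number as a block it was 0.0550 for the probe set at 71.5%, no longer past the threshold, and that probe set had the dimmest signal, close to the bacterial controls. An exact two-sided permutation test gave 0.1 for each probe set, the smallest value that 3 against 3 arrays allow. The fall of the brightest probe set differed between pairs, at -0.28, -1.05 and -0.70 for pairs 1, 2 and 3. Its unadjusted p of 0.0302 in the gene fit rose to 0.0826 without control array 1, 0.0554 without control array 2, 0.0746 without control array 3, 0.0559 without REST shRNA array 2 and 0.0614 without REST shRNA array 3.

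Over all 18194 genes, no gene passed the adjusted threshold of 0.05 in either direction with limma. The genes with the smallest p among those higher in REST shRNA were Hpca, St8sia3, Ap3b2, Rgs4 and Chga. Hpca, which encodes the neuronal calcium sensor hippocalcin, read 4.46-fold higher (log2 difference 2.16, 95% CI 1.56 to 2.76). St8sia3, a sialyltransferase of the brain, read 5.04-fold higher (log2 difference 2.33, 95% CI 1.62 to 3.05). Ap3b2, the neuronal subunit of an adaptor complex that sorts vesicle cargo, read 2.10-fold higher, Rgs4, a regulator of G protein signalling, 2.32-fold higher, and Chga, which encodes chromogranin A of dense core vesicles, 3.09-fold higher. For each of these 5 genes the adjusted p was 0.658, the smallest of the whole table, so all 5 missed the threshold. Ap3b2 has a second, dim probe set with a log2 difference of -0.05. The 5 genes with the smallest p among those lower in REST shRNA also missed the threshold. They were Pcdhb22, a clustered protocadherin, at -0.77 ± 0.14 (SE, log2), Fndc9 at -1.19 ± 0.22, Akap5, which anchors protein kinase A, at -0.71 ± 0.14, Prkcd, protein kinase C delta, at -0.77 ± 0.16, and Lpar4, a lysophosphatidic acid receptor, at -0.70 ± 0.15. A second, dimmer probe set of Prkcd differed by only -0.09.

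**Figure D1:**
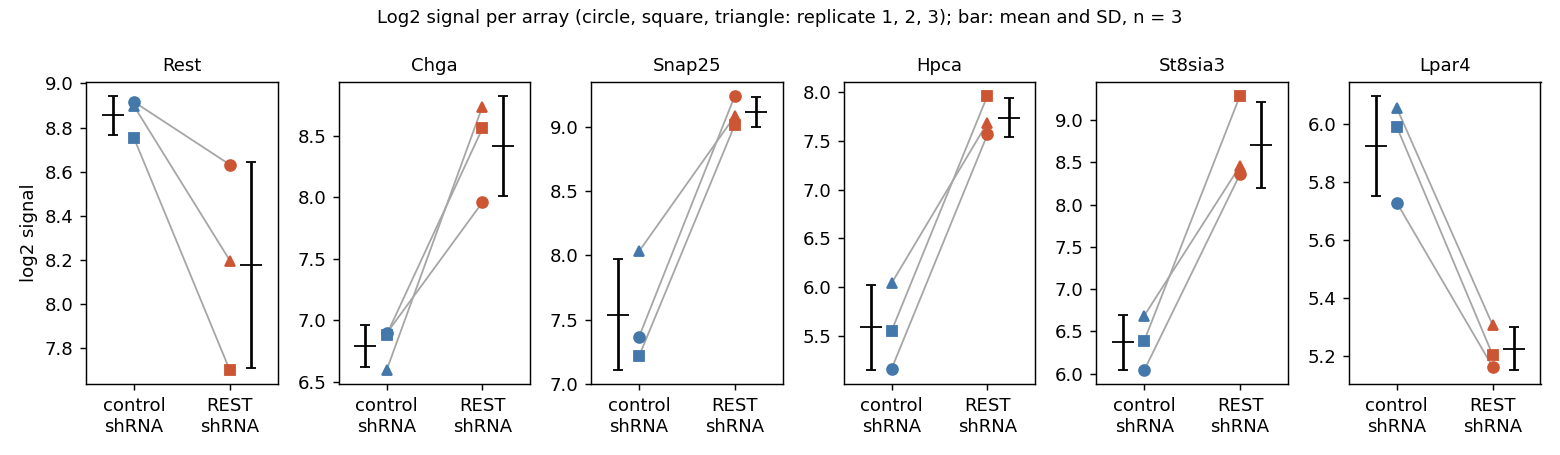
Log2 signal of Rest and of 5 other genes in each array, with control shRNA on the left and REST shRNA on the right of each panel, lines joining arrays with the same replicate number, and bars for the mean and SD of 3 arrays. Rest lies lower in all 3 REST shRNA arrays than in any control array, Chga, Snap25, Hpca and St8sia3 lie higher in all 3, and Lpar4 lies lower in all 3, while none of the 6 genes passed the threshold adjusted over all genes.

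At an unadjusted p under 0.05, 323 genes were higher and 195 lower, together 2.85% of genes where chance alone gives 5%, or 910 genes. With the replicate number as a block the adjusted count stayed at 0, with 407 genes higher and 258 lower at the unadjusted threshold. Centring each array on its median gave 414 higher and 149 lower. The counts were 175 and 100 without control array 1, 220 and 166 without control array 2, 643 and 357 without REST shRNA array 1, and 768 and 296 without REST shRNA array 2. An unequal-variance test per gene called 1 gene higher, A4galt, and 1 lower, Mthfs, both at an adjusted p of 0.0338. These genes were looked up after their values were seen, lie below or about the highest bacterial control signal of 3.24, and had log2 differences of 0.44 and -0.44. The 2 groups did not overlap for 1376 genes, 7.56% of the genes against 10% by chance, and 893 of these were higher in REST shRNA.

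Known target genes of REST were higher in the REST shRNA arrays. The list held 51 measured genes with RE1 sites, most of them neuron-enriched, and 44 of them had a positive log2 difference, with a median of 0.65. No member was called over all genes tested, while 16 members rose when adjusted over the list alone and no member fell. The 16 were 4 genes of dense core vesicles (Chga, Chgb, Scg2 and Scg3), 6 genes of synaptic vesicle release or the presynaptic zone (Snap25, Syn1, Bsn, Rph3a, Unc13a and Cplx1), and Celsr3, Chrnb2, Stmn3, Cdk5r2, Disp2 and Olfm3. Snap25, a SNARE protein of synaptic vesicle fusion, read 7.54 ± 0.43 (SD, n = 3) in control and 9.12 ± 0.12 (SD, n = 3) in REST shRNA, 2.99-fold higher, with a list-alone adjusted p of 0.00513 in limma. Chga had the same adjusted p, and its log2 differences in pairs 1, 2 and 3 were 1.06, 1.68 and 2.14. Other members of the list gave no sign of a difference: Gad1, which makes GABA, differed by -0.02 ± 0.21 (SE, log2), Scn3a by 0.06 ± 0.37, Bdnf by -0.16 ± 0.25 and Gria2 by -0.43 ± 0.31, while second probe sets differed by 0.52 for Gad1, -0.32 for Scn3a and 0.20 for Bdnf, the last 2 near background. Stmn2 and Syt4, at 1.90 ± 0.85 and 1.92 ± 0.66, were among the largest differences of the list but missed the threshold, and both passed it with the replicate number as a block (adjusted p = 0.0388 and 0.0123 over the list alone), where 21 members rose.

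As a set, the REST targets ranked above other genes in the camera test with a preset correlation between genes of 0.01 (adjusted p = 6.15e-23 over 22 lists). With an estimated correlation the call was lost (adjusted p = 0.128). The fry test, which asks whether the genes of a list move one way on balance, gave an adjusted p of 0.0481, and 0.333 with the replicate number as a block. That call also ended without control array 1 (adjusted p = 0.280), control array 2 (0.0952), control array 3 (0.108) or REST shRNA array 2 (0.141), with each array centred on its median (0.0728), without probe sets that can match several transcripts (0.0520), and with the cell cycle (0.103) or Gapdh (0.151) covariate. The fry test of change in either direction gave 0.00664 for the list, and 0.0707 with the block. At the unadjusted threshold 22 of the 51 members were higher, 43.1% of the list against 1.66% of the other genes (Fisher's exact test, two-sided, p = 1.46e-25, which treats genes as independent). The mean difference of the list was 0.65, 0.66 and 0.86 in pairs 1, 2 and 3. The number of members that rose, adjusted over the list alone, was 8 without control array 1 and 25 without REST shRNA array 2. It was 5 without both arrays numbered 1, 5 without both arrays numbered 3, and 0 with the unequal-variance test per gene. The list median was 0.42 without REST shRNA array 3.

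General neuronal markers also stood higher. Of 29 measured members, 22 had a positive difference, with a median of 0.30, and the camera test with the preset correlation called the list (adjusted p = 2.74e-06, or adjusted p = 0.441 with an estimated correlation). No member passed when adjusted over the list alone. With the replicate number as a block 4 members rose, adjusted over the list alone, and these were Crmp1, Stmn4, Gap43 and Nefl. Without REST shRNA array 2 the count was 14, and without REST shRNA array 1 it was 2. The list median was 0.64 without REST shRNA array 2, 0.65 without both arrays numbered 2 and 0.17 without REST shRNA array 3. The list stayed called in each with the preset correlation. With an estimated correlation it was called in none of these (camera adjusted p = 0.373, 0.704 and 0.529). Crmp1, a collapsin response mediator, read 1.82-fold higher and Stmn4, a stathmin that binds tubulin, 2.73-fold higher. Dcx and Map2, further neuronal markers, differed by -0.20 ± 0.54 (SE, log2) and -0.10 ± 0.17, and another probe set of Dcx read 0.02 higher. The list mean differed by 0.62, 0.02 and 0.60 in pairs 1, 2 and 3, so in pair 2 the neuronal markers stood level while the REST targets did not.

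The other neuronal lists gave no call with the preset correlation, and for some of them that rested on the settings. In the synaptic vesicle list 23 of 33 members had a positive difference, with a median of 0.16 (adjusted p = 0.0623), and Cadps and Cplx2, both factors of vesicle release, differed by 0.86 ± 0.24 (SE, log2) and 0.66 ± 0.22. The list was called without REST shRNA array 2 (median 0.33, adjusted p = 0.000123) and without control array 3 (median 0.14, adjusted p = 0.0148), or adjusted p = 0.373 and adjusted p = 0.737 with an estimated correlation. It was also called in 10 other alternatives, among them quantile normalization (adjusted p = 0.0431), the mean over all probe sets of a gene (0.00353) and array weights (0.000134), and with an estimated correlation in none (adjusted p at least 0.300). In the ion channel list the median was 0.13 over 29 members (adjusted p = 0.175), and the list was called with the most variable probe set per gene (adjusted p = 0.0385) and with every probe set tested (0.00372), or adjusted p = 0.366 and adjusted p = 0.361 with an estimated correlation. Its Cacna1b, a subunit of N-type calcium channels, rose 2.41-fold adjusted over the list alone (adjusted p = 0.00966), and Kcnip1 differed by 0.96 ± 0.29. A fry test of change in either direction gave an adjusted p of 0.0270 for the ion channels with the replicate number as a block and 0.919 without it. Neurotransmitter receptors had a median of 0.02 over 25 members (adjusted p = 0.804), with Gria1 at 0.65 ± 0.26 and Grin2b at 0.65 ± 0.27. Factors of early neurogenesis had a median of 0.09 and a camera direction that was downward (adjusted p = 0.804), with Isl1 at 0.34 ± 0.15 below background and Pou4f1 at -0.46 ± 0.21, with a second, dim probe set at 0.25. Without REST shRNA array 3 their median was -0.06 (adjusted p = 0.0296, or adjusted p = 0.532 with an estimated correlation).

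**Figure D2:**
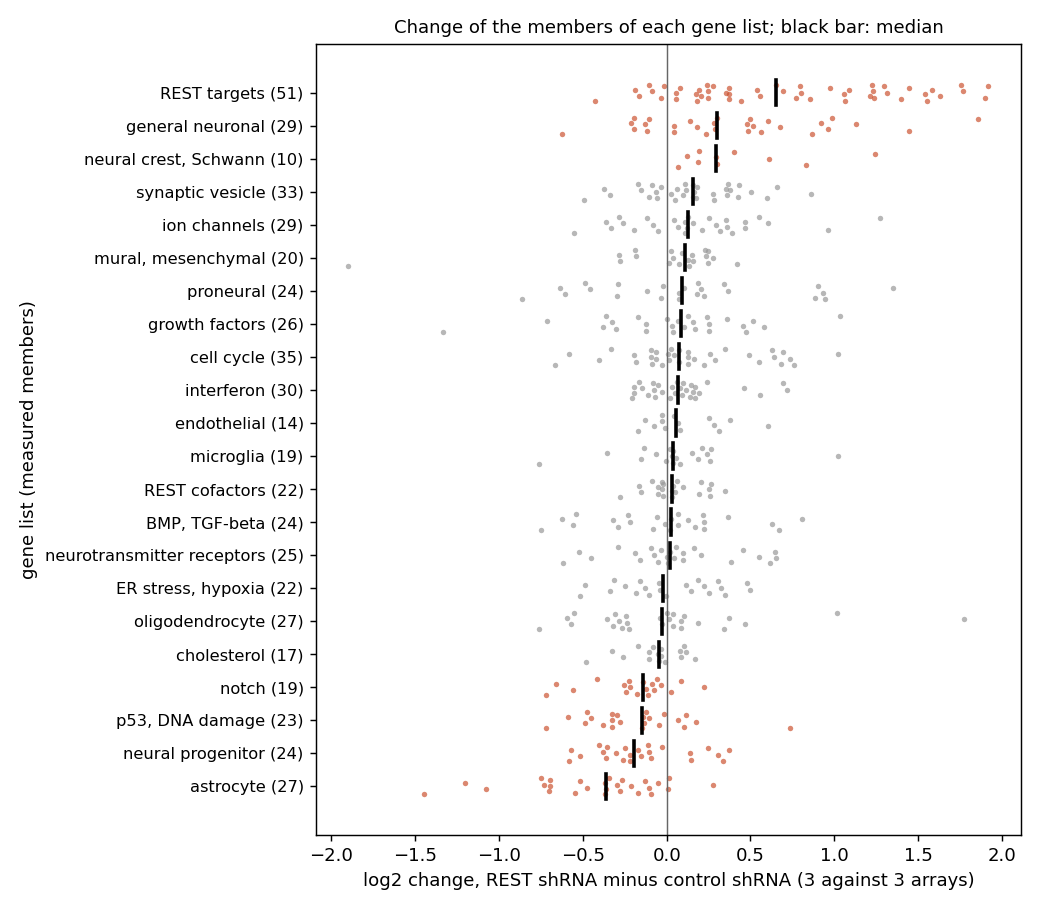
Log2 difference between REST shRNA and control shRNA (3 against 3 arrays, horizontal axis) for every measured member of 22 gene lists, with the list median as a black bar, and in orange the 7 lists called by the camera test with the preset correlation. The REST targets have the highest median, at 0.65, and the astrocyte markers the lowest, at -0.36, and with an estimated correlation none of the 22 lists was called.

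Neural progenitor and astrocyte markers stood lower, the progenitor markers mainly in pairs 1 and 2 and the astrocyte markers through 1 array. Oligodendrocyte markers did not, and no member of these 3 lists passed when adjusted over its list alone. Of 24 neural progenitor markers, 18 had a negative difference, with a median of -0.19 (adjusted p = 0.00299, or adjusted p = 0.332 with an estimated correlation). Ptprz1, a receptor phosphatase of radial glia, differed by -0.35 ± 0.14 (SE, log2) and Fabp7, a fatty acid binding protein of radial glia, by -0.40 ± 0.24. The progenitor list mean differed by -0.21, -0.21 and -0.02 in pairs 1, 2 and 3, and 10 of the 24 members were higher in pair 3. Without REST shRNA array 1 the progenitor call ended (adjusted p = 0.138), with a median of -0.25. The median was -0.09 without REST shRNA array 2 and -0.30 without REST shRNA array 3, with the call kept at the preset correlation. With an estimated correlation these were camera adjusted p = 0.373 and adjusted p = 0.32. Astrocyte markers had a median of -0.36, with 24 of 27 members negative (adjusted p = 7.47e-05, or adjusted p = 0.565 with an estimated correlation), and Slc1a2 and Fgfr3 differed by -0.70 ± 0.20 and -0.70 ± 0.34. That shift lay in REST shRNA array 2: the list mean differed by -0.04, -1.47 and 0.22 in pairs 1, 2 and 3, and without that array the median was 0.02 (adjusted p = 0.957). It was -0.55 without REST shRNA array 1. Of the 27 members, 4 were lower in every pair, Slc1a2 and Fgfr3 among them, about as many as random signs would give. In every pair 0 were higher. Slc1a2, the member with the smallest p, differed by -0.54, -1.02 and -0.53, so its difference did not rest on REST shRNA array 2 alone. Oligodendrocyte markers had a median of -0.03 over 27 members (adjusted p = 0.497), 0.36 without REST shRNA array 2 (adjusted p = 0.000979) and -0.57 without REST shRNA array 3 (adjusted p = 1.68e-05). These were adjusted p = 0.609 and adjusted p = 0.529 with an estimated correlation. Mobp, a myelin protein, differed by 1.77 ± 1.02 and rose, adjusted over the list alone, with the replicate number as a block (adjusted p = 0.0187), and Sox8 differed by -0.36 ± 0.26.

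In 3 further lists the camera test with the preset correlation made a call, again with no member past the threshold adjusted over its list alone. Notch pathway genes had a median of -0.14, with 16 of 19 negative (adjusted p = 0.00326, or adjusted p = 0.441 with an estimated correlation), and Hey2 and Nrarp, both Notch response genes, differed by -0.72 ± 0.39 (SE, log2) and -0.56 ± 0.31. The call ended without control array 1 (adjusted p = 0.0548) and without REST shRNA array 1 (adjusted p = 0.0709), with the stricter filter on dim genes (0.0506), and with every probe set tested (0.0646), while the medians were -0.14, -0.15, -0.14 and -0.12. Without control array 3 the median was -0.25, and without both arrays numbered 3 it was -0.27. The Notch list mean differed by -0.36, -0.38 and 0.15 in pairs 1, 2 and 3, so the shift was absent in pair 3. The p53 and DNA damage genes had a median of -0.14, with 18 of 23 negative (adjusted p = 0.00299, or adjusted p = 0.441 with an estimated correlation), Trp53inp1 at -0.59 ± 0.19 and Ccng1 at -0.45 ± 0.25. Their median was -0.03 without REST shRNA array 1 (adjusted p = 0.383) and -0.06 without control array 2 (adjusted p = 0.167). It was -0.29 without control array 1, -0.30 without control array 3, -0.22 without REST shRNA array 3 and -0.31 without both arrays numbered 3. The p53 list mean differed by -0.41, -0.16 and 0.03 in pairs 1, 2 and 3. Neural crest and Schwann cell markers had a median of 0.30, with all 10 measured members positive (adjusted p = 0.0186, or adjusted p = 0.332 with an estimated correlation), Pou3f1 at 1.24 ± 0.77 and Erbb3 at 0.83 ± 0.53. That call ended without control array 1 (adjusted p = 0.0600), control array 2 (0.0926), REST shRNA array 2 (0.0602) or REST shRNA array 3 (0.0681), with the milder filter on dim genes (0.0946), with the mean over all probe sets of a gene (0.0646) and with the most variable probe set per gene (0.263). The medians without these arrays were 0.24, 0.25, 0.28 and 0.17, and with these settings 0.46, 0.21 and 0.18. Of these 10 markers, 6 had a mean above the highest bacterial control, and 2 were higher in all 3 pairs. Pou3f1 read 7.02 in REST shRNA array 2 and at most 4.67 in the other arrays.

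The remaining lists were not called, some of them depending on the arrays or probe sets used. S phase and mitosis genes had a median of 0.08 over 35 members (adjusted p = 0.799), with Tyms at 0.68 ± 0.44 (SE, log2) and Ccne2 at 0.74 ± 0.50. Their median turned to -0.76 without REST shRNA array 2 (adjusted p = 1.42e-05) and -0.72 without control array 3 (adjusted p = 0.0143), and was 1.00 without REST shRNA array 3 (adjusted p = 2.01e-06). With an estimated correlation these were adjusted p = 0.635, adjusted p = 0.857 and adjusted p = 0.578. Interferon-stimulated genes, a known reaction to viral RNA, had a median of 0.07 over 30 members (adjusted p = 0.804), with Ifit2 at 0.72 ± 0.48 and Zbp1 at 0.20 ± 0.16, with a second, dim probe set at -0.13. REST cofactors had a median of 0.03 over 22 members (adjusted p = 0.804). The 2 members with the smallest p in that list were Smarce1, of a chromatin remodelling complex, at 0.26 ± 0.15, with a second probe set at -0.38, and Tefm at 0.35 ± 0.17, a mitochondrial transcription factor that is not known as a partner of REST. BMP and TGF-beta genes had a median of 0.02 and a downward camera direction (adjusted p = 0.799), and -0.43 with the stricter filter on dim genes (adjusted p = 0.00082, or adjusted p = 0.302 with an estimated correlation), with Bmper at -0.75 ± 0.23 and Bmpr1b at -0.63 ± 0.27. Secreted growth factors had a median of 0.09 (adjusted p = 0.799), with Sema3c at 0.51 ± 0.18, below background, and Igf2 at 0.58 ± 0.29. Cholesterol synthesis genes had a median of -0.05 (adjusted p = 0.497), with Stard4 at -0.48 ± 0.69 and Idi1 at -0.33 ± 0.55. That list was called without REST shRNA array 2 (median -0.47, adjusted p = 1.34e-06) and without control array 3 (median -0.38, adjusted p = 0.000309), or adjusted p = 0.581 and adjusted p = 0.737 with an estimated correlation. It was also called with array weights (adjusted p = 1.01e-06), without both arrays numbered 2 (0.00232) and with the cell cycle (0.00621) or Gapdh (0.0136) covariate, and with an estimated correlation in none of these (adjusted p at least 0.465). Genes of endoplasmic reticulum stress and hypoxia had a median of -0.02 and a mean of 0.01 (adjusted p = 0.804), with Car9 at -0.49 ± 0.36 and Atf3 at -0.52 ± 0.41.

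Markers of microglia, endothelium and mural or mesenchymal cells, which the cultures could hold, were not called with 1 probe set per gene, and many of them read low. With every probe set tested, the endothelial (adjusted p = 0.0475) and mural (adjusted p = 0.0283) lists were called, or adjusted p = 0.361 each with an estimated correlation. Only 9 of 19 microglial, 4 of 14 endothelial and 10 of 20 mural or mesenchymal markers had a mean above the highest bacterial control. The medians were 0.04 for microglia (adjusted p = 0.799), 0.06 for endothelium (adjusted p = 0.497), and 0.11 for mural and mesenchymal genes (adjusted p = 0.804), whose mean was -0.02. Aif1 differed by 1.02 ± 0.30 (SE, log2), with a mean below background, and Cd68 by -0.76 ± 0.36. Sox17 and Vwf, at 0.38 ± 0.16 and 0.60 ± 0.36, also had means below background. Col1a1 and Rgs5 differed by 0.42 ± 0.17 and -0.28 ± 0.16, and dim probe sets of Rgs5 by 0.51 and 0.18. Among the brighter mural markers, chosen after their values were seen, Fbln1 read 6.72 in control and 6.97 in REST shRNA, Pdgfrb 5.86 and 6.14, and Acta2, the smooth muscle actin, differed by -1.90 ± 1.60, with -4.94 in pair 1 and -0.40 and -0.37 in pairs 2 and 3 and a dim probe set at 0.40.

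Arrays within a group were not alike. The first principal component over genes held 51.6% of the variance and set REST shRNA array 2, at -68.0, apart from the other arrays, which lay between -12.1 and 39.6. In that array Gfap, the astrocyte filament protein, read 5.58 against 8.85 to 11.7 in the others, the astrocyte list mean was 7.49 and the cell cycle list mean was 9.05. Both arrays numbered 3 had low cell cycle list means, 5.85 in control and 5.81 in REST shRNA, against 7.26 to 9.05 in the other arrays. The REST target mean lay between 5.86 and 5.96 in the control arrays and between 6.51 and 6.81 in the REST shRNA arrays.

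**Figure D3:**
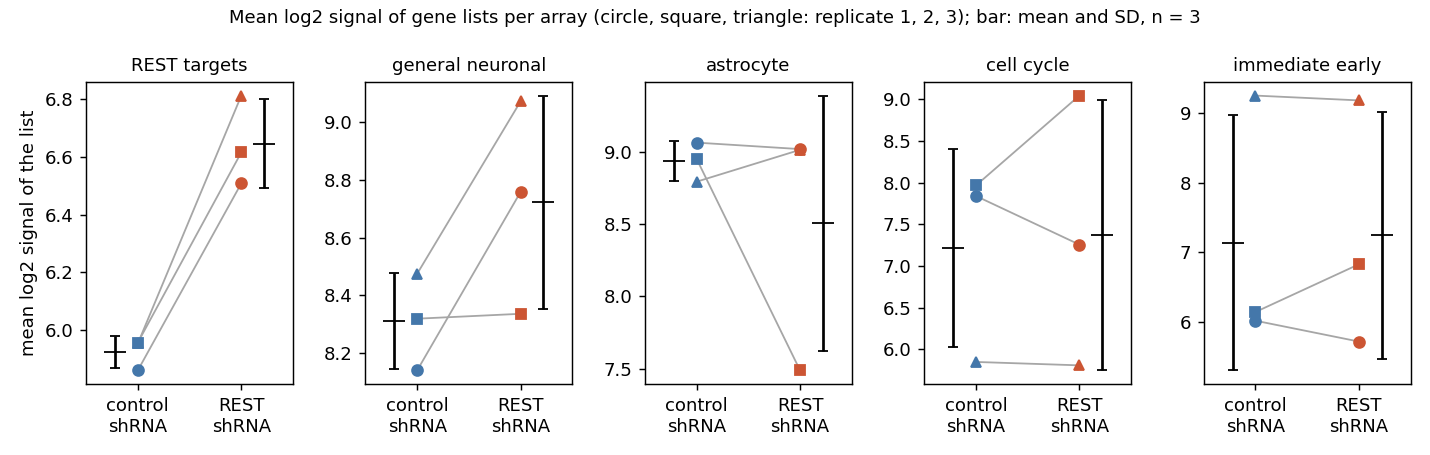
Mean log2 signal per array of 5 gene lists, with control shRNA on the left and REST shRNA on the right, lines joining arrays with the same replicate number, and bars for the mean and SD of 3 arrays. The REST target mean is higher in all 3 REST shRNA arrays, while the astrocyte mean of 7.49 and the cell cycle mean of 9.05 set REST shRNA array 2 apart and the immediate early mean sets both arrays numbered 3 apart.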

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

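The alternatives that leave out both arrays of a number or add a covariate were chosen after seeing the data. All 25 alternatives left 0 genes past the adjusted threshold in each direction, except the unequal-variance test, which called 1 higher and 1 lower. Smallest adjusted p values ranged from 0.0338 to 1. Where genes were tested, counts at the unadjusted threshold ranged from 115 to 768 genes higher and 88 to 370 lower. With every probe set tested separately, 692 probe sets were higher and 869 lower. The REST target median stayed positive (0.42 to 0.82) and past the camera threshold with the preset correlation in all 24 alternatives that test lists, and with an estimated correlation in none (adjusted p at least 0.058). With that correlation no alternative called any list. The fry call of the REST targets ranged in adjusted p from 0.0126 to 0.589 and ended in 12 of the 24 alternatives, those in the report and without both arrays numbered 1 (0.589), 2 (0.289) or 3 (0.0995). The members that rose, adjusted over the list alone, ranged from 8 to 25 when 1 array was left out, were 5 without both arrays numbered 1, 5 without both numbered 3, and 0 with the unequal-variance test, which estimates the spread of each gene from 3 arrays a group. The 7 lists called became 4 to 10 when 1 array was left out and 3 without both arrays numbered 1. The Rest difference stayed negative throughout and ranged from -0.91 to -0.44 when 1 array was left out. It missed its unadjusted threshold when any 1 array except REST shRNA array 1 was left out. It also missed it with the unequal-variance test (-0.68), without both arrays numbered 2 (-0.49) or 3 (-0.67), where fewer arrays were tested, and with the Gapdh covariate (-0.67). Its unadjusted p ranged from 0.00248 to 0.126 over all alternatives.

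List medians turned sign in some alternative for 14 lists (49 values), and among the lists called only for astrocyte genes. When 1 array was left out, medians ranged from -0.57 to 0.36 for oligodendrocyte, from -0.55 to 0.018 for astrocyte, from -0.76 to 1.00 for cell cycle and from -0.061 to 0.19 for proneural genes, with the arrays named in the report. Without both arrays numbered 2 the medians were 0.34 for oligodendrocyte, 0.098 for astrocyte and -0.37 for cell cycle genes. The cell cycle median was -0.73 with array weights, which gave REST shRNA array 2 the lowest weight, 0.314. The BMP and TGF-beta median was -0.43 when the dimmer genes were left out by the stricter filter, where fewer genes were tested, and that of growth factors was -0.32 and of proneural genes -0.16. The cholesterol median was 0.20 without both arrays numbered 1. Beyond the arrays or genes left out, the cause was not tested. That filter left too few microglial, endothelial, interferon and neural crest genes, and these lists were not tested in it. With the replicate block the same 7 lists were called, and the block changed no other reported call than those given in the report and for Celf4. Without both arrays numbered 1 the progenitor, p53, Notch and neural crest calls ended. Of 53 named genes, 7 changed sign in some alternative and none was called in any. Pseudocounts planned for linear values were not run, since the values are log2, and the unequal-variance test gives no list test. No scaling moved the median of all genes beyond 0.0756. Signal over background limits the genes under the bacterial reference.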

Other observations

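The tests and genes in this part were chosen after the results were seen, except the count of splits for genes past the threshold. In 18 genes the REST shRNA array read at least 2-fold higher than the control array in every pair, and in 0 genes at least 2-fold lower in every pair. The 18 were Hpca, St8sia3, Slc7a14, Myh7, Syt4, Nefl, Mobp, Celsr3, Syndig1l, Resp18, Jph4, Chga, Snap25, Zdhhc22, Scg2, Cacna1b, Chgb and Camk2n2. Of these, 6 are in the REST target list, more than chance gives (Fisher's exact test, two-sided, p = 6.47e-12, which treats genes as independent), and 12 are not. Slc7a14 read 4.17 ± 0.20 (SD, n = 3) in control and 6.22 ± 0.58 (SD, n = 3) in REST shRNA. Myh7, a cardiac and slow muscle myosin, differed by 1.37, 2.88 and 2.68 in pairs 1, 2 and 3, and Mobp, a myelin protein, by 2.31, 1.09 and 1.92, although Mobp missed the unadjusted threshold between the groups. None of the 18 passed the threshold adjusted over all genes. Turning the labels of 1 pair gave at most 6 such genes in a direction, against 18, and 1 of the 4 ways to label the pairs gave as many, too few ways to exclude chance.

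Some regulators of splicing stood higher and others did not. Among the 6 Celf genes, which encode RNA-binding regulators of splicing, Celf3, Celf5 and Celf6 read 0.87 ± 0.26 (SE, log2), 0.60 ± 0.16 and 0.82 ± 0.26 higher (limma adjusted p = 0.0312 each over the 6 genes). These families were put together after the values were seen, so their adjusted p values describe the genes and do not test them. Celf4 read 0.98 ± 0.39 higher (adjusted p = 0.0603, or 0.0338 with the replicate number as a block), Celf1 0.15 ± 0.18 higher and Celf2 -0.30 ± 0.18, with signs that held under each scaling, while 2 dimmer probe sets of Celf2 read 0.06 and 0.32 higher. Srrm3, a splicing factor of neuronal microexons, read 1.44 ± 0.34 higher (adjusted p = 0.0162 over 4 Srrm genes). The probe sets of its relative Srrm4 disagreed, with -0.03 ± 0.21 for the brightest and 0.89 ± 0.29 and 0.94 ± 0.30 for the others. The brightest is of the kind that can match several transcripts, and the others are not. Among 11 Nova, Rbfox, Elavl and Ptbp genes none was under the threshold within the family (smallest adjusted p = 0.102, for Rbfox2 at 0.47 and Rbfox3 at 0.92), and Nova1 differed by -0.39. Of secretory genes related to the granins among the REST targets, Vgf differed by -0.04, 3.63 and 1.67 in pairs 1, 2 and 3, and Scg5 and Pcsk1n by 0.16 ± 0.59 and 0.08 ± 0.38.

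The REST targets stood higher in the REST shRNA arrays by a median of 0.65. RNA degradation and cell cycle state were each looked at as a cause. The Gapdh 3' minus 5' signal differed by -0.008, 0.216 and -0.62 in pairs 1, 2 and 3. The cell cycle list mean differed by -0.585, 1.08 and -0.041. Neither moved one way, while the REST target mean was higher in every pair. The pairs argue against either measure as the whole cause, but rest on 1 control gene and 1 list, so neither cause is excluded. As covariates, the Gapdh signal gave a median of 0.668 and the cell cycle list mean one of 0.614. The lowest medians when any 1 array was left out as well were 0.376 and 0.410. Both covariates differed little between the groups against their spread, so these fits could hardly move the median and decide little. A larger share of neurons in the REST shRNA samples stays open as part of the cause. The REST targets exceeded the general neuronal markers by 0.03, 0.64 and 0.26 in pairs 1, 2 and 3. The mean of 0.308 was no larger than its SD of 0.310. This comparison cannot decide, since REST keeps many neuronal genes low and the markers could rise with either cause. In pair 2 the REST targets differed by 0.66 and the markers by 0.02. A larger share of neurons did not show in the markers there. The REST shRNA itself stays open too, and no test run here separates it from a change in the share of neurons. Of the 10 splits of the 6 arrays, 1, the real one, gave a median as large, with 0.31 the highest of the others, and 16 against 0 members past the threshold adjusted over the list alone, again in 1 of 10 splits, too few splits to exclude chance.

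REST shRNA array 2 stood apart in astrocyte genes, with Gfap at 5.58 (a second probe set had the opposite sign between groups, at 0.04) and Aqp4 at 6.05, and in cell cycle genes. RNA degradation in that array was argued against by Gapdh alone, because its 3' minus 5' signal of 1.93 lay within the range of the other arrays, 1.72 to 2.87. The top of that range came from the arrays numbered 3, while control array 1 read 1.94. In REST shRNA array 2 the beta-actin 3' minus 5' value of 0.367 was level with the highest of the others, so degradation was not excluded. A control array under a REST shRNA label was argued against too, because its REST target mean of 6.62 lay above every control array and its Rest signal of 7.70 was the lowest of all. In pair 2 astrocyte genes differed by -1.47, oligodendrocyte genes by -0.87 and general neuronal genes by 0.02. Whether this reflects the REST shRNA or the state of that culture was not tested, since the other REST shRNA arrays did not show it.

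Both arrays numbered 3 had high immediate early genes, which respond within minutes to stimulation or handling, with a mean over 14 genes of 9.25 and 9.18 against 5.72 to 6.83 in the others, and Fos at 12.2 and 12.1 against 6.75 to 7.24. The REST shRNA was argued against as the source, because the immediate early mean differed by -0.069 within pair 3 and by 3.03 between pair 3 and the other arrays. RNA degradation in those arrays could not be decided: the Gapdh 3' minus 5' signal was at least 2.25 in them and at most 1.94 in the others, while the lower beta-actin value in them, 0.324, lay under the 0.367 reached in the others. A shared difference in culture density or handling on another day may also account for it and was not tested, as the labels name no batch.

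Splits of the arrays bear on the other counts as well. The real split gave 0 genes past the adjusted threshold and 10 of 10 splits gave as many, the highest other count being 2, for control arrays 1 and 2 with REST shRNA array 2 against the rest. That split gave 2294 genes at the unadjusted threshold against 518 for the real one, the highest count of the 10 splits. It has both arrays numbered 3 and REST shRNA array 1 on one side. More genes thus followed it than the groups, but it also parts the groups in part, so it cannot show a structure unrelated to them. Among the splits that part all 3 pairs, the others gave 0 genes past the adjusted threshold and REST target medians of 0.06, 0.22 and 0.22 in size. For the 7 lists called with the preset correlation, 4 of 10 splits gave as many and the highest other gave 8, so that count does not stand out from other splits, and 10 splits are too few to exclude chance. The 10143 probe sets with no gene or several genes held 0 past the adjusted threshold, with a smallest adjusted p of 0.992, and 418 at the unadjusted one.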
